A study of Mus musculus with 9 samples.

How the data were processed

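CITE-seq, which reads transcripts and antibody tags from the same cells, was performed on total splenocytes of mice that were wild type (WT), heterozygous (R594C/+) or homozygous (R594C/R594C) for the R594C change in IRE1, the endoplasmic reticulum (ER) stress sensor encoded by Ern1. Per the labels, the cells were sorted with DAPI, a dye that marks dead cells, and loaded on a 10x Genomics droplet instrument with the 3' NextGEM 3.1 chemistry. Each genotype was 1 capture, and each capture was deposited as an mRNA, an antibody tag and a hashtag library, which makes 9 samples in GEO. The hashtag labels give replicates 1 to 4 in WT and in R594C/+ and replicates 1 and 2 in R594C/R594C. The labels speak of replicates and do not say that each is a separate animal, so p-values measure only the spread between these samples. Because each genotype was stained and captured by itself, genotype, capture and staining tube cannot be told apart.

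The authors deposited raw UMI counts (UMIs are molecular tags that mark original molecules) per gene, antibody and hashtag for each barcode. Per the file headers, the count matrices came from Cell Ranger 5.0.0. Per the submitters' processing notes, Cell Ranger, STAR, Seurat 3.1.4 and the mouse build mm10 were used, with no role or order given. The filters behind the barcodes are not given in the sources used here, but no barcode held fewer than 500 RNA UMIs. The count files hold 55385 genes, 191 antibodies and 24 hashtags. Gene symbols were taken from the files. Gene positions were taken from the RefSeq table of assembly GRCm38.p6, the assembly of which mm10 is another name.

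Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept. Hashtags were called with Seurat 5.3.0 (HTODemux, quantile 0.99), which left 12759 single cells in WT, 15344 in R594C/+ and 15502 in R594C/R594C, with 1295, 1837 and 1543 doublets of different hashtags and 1763, 591 and 193 barcodes with no hashtag. Doublets within a hashtag were scored against simulated doublets (2 per barcode, expected rate 10%), and 2.81%, 3.15% and 7.29% of the single cells were removed. The share expected from the hashtag doublets was 3.38%, 3.99% and 9.95%, so some doublets remained. The remaining 41633 cells were clustered on 2000 variable genes (antigen receptor segments and sex-linked genes left out), 30 principal components and 20 neighbours (scikit-learn 1.9.0) with Leiden clustering at resolution 1.5 (leidenalg 0.10.2, igraph 0.11.9, seed 1), which gave 37 clusters. A cluster was called "X-like" from fixed marker genes found at 2-fold or more over the other cells in at least 10% of its cells. Clusters without a clear set of markers kept a number.

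Counts were summed per replicate and class, in replicates with at least 10 cells of the class. The main test was edgeR 4.0.16 (robust quasi-likelihood, TMM scaling, filterByExpr) over all 10 replicates, with Benjamini-Hochberg adjustment at 0.05. Antibody tags were tested in the same way, for antibodies with a mean of at least 10 UMIs per replicate. The 32 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry. Shares of cells were tested with a two-sided exact permutation test of their correlation with the number of R594C alleles, over 3150 assignments, with a smallest possible p of 0.000317. Differences between classes were tested with edgeR as an interaction, with each replicate as a block. The tests were first tried on counts simulated at the real library sizes. There 100% of 100 genes changed 2-fold were recovered in follicular-like B cells for R594C/R594C minus WT. In plasma cell-like cells the same comparison recovered 52% of 2-fold and 92% of 4-fold changes. Recovery of genes with low counts was not measured apart. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.

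The lists were XBP1s targets and secretory pathway, ER chaperones under ATF6, ATF4 and CHOP targets, substrates of IRE1-dependent RNA decay (RIDD), type I interferon response, interferon gamma response, MHC class II presentation, B cell receptor activation, immediate early and heat shock genes, plasma cell programme, immunoglobulin constant genes, marginal zone B programme, age-associated B programme, germinal centre programme, proliferation, NF-kB and survival in B cells, B cell inhibitory receptors, T follicular helper, regulatory T, T cell activation and memory, naive T, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, cytosolic ribosomal proteins, mitochondrially encoded genes, sex-linked genes, and genes of erythroid cells, neutrophils, T cells, B cells, and monocytes and macrophages as signs of other cells or free RNA. Named genes followed a rule: Ern1 and Xbp1 in each tested class; the 8 highest and 8 lowest folds in follicular-like and marginal zone-like B cells for R594C/R594C minus WT, and the 3 highest and 3 lowest elsewhere, among genes past 0.05 with a mean log2 CPM of at least 4 and no overlap between replicates; and up to 3 members per list with the smallest p. Receptor segments were counted apart. Up to 5 antibodies per direction were named. The groups, tests, lists, markers, naming rule and most alternatives were chosen before the data were examined.

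The alternatives were stricter cell filters (500 genes, 5% mitochondrial UMIs), a margin rule for hashtags (3-fold and 20 UMIs), classes defined on WT cells and passed on through 15 neighbours, doublets kept, cells thinned to equal UMIs, RLE scaling, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, each replicate left out, only antibodies above the isotype controls, another statistic or denominator for the shares, and a surface gate. Further choices were made after the data were seen. These were expressed sex (Xist and Y-linked transcripts) as a covariate, permutation within expressed sex, tests in B1-like cells, and list tests in plasma cell-like, B1-like and CD8 T-like cells. B1-like cells were added after the counts of all classes had been viewed, because they had the largest number of changed genes between R594C/R594C and WT. For conventional dendritic-like cells (64, 72 and 56 cells in WT, R594C/+ and R594C/R594C), counts simulated for 3895 genes gave back 38% of changes of 1 and 76% of changes of 2 on the log2 scale for R594C/R594C minus WT, and 41% and 85% for R594C/+ minus WT.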

Results

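CITE-seq profiles were collected from spleens of 10 replicates in 3 droplet captures. The captures held 16027 barcodes for WT (4 replicates), 17980 for R594C/+ (4 replicates) and 17444 for R594C/R594C (2 replicates), with 74546390, 87953814 and 74538447 RNA UMIs and 7427955, 8875461 and 8702246 antibody tag UMIs. The median cell held 3483, 3448.5 and 3166 RNA UMIs and 1467, 1453 and 1365 genes, and the median mitochondrial share was 1.91%, 1.79% and 2.07%. After filtering, a replicate had 2954 to 7436 cells and 13166724 to 28521373 RNA UMIs. The study asked whether the R594C change in IRE1 affects the immune cells of the spleen. Its title concerns the splicing of Xbp1, the messenger RNA that active IRE1 cleaves to make the transcription factor XBP1s, and B cell tolerance.

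Transcripts of the mutated gene and of its best known substrate were read first. Ern1 lies on chromosome 11 (106397620 to 106487796, GRCm38.p6) and Xbp1 on the same chromosome (5520641 to 5525993). In plasma cell-like cells Ern1 was at 22.2 ± 8.91 CPM in WT, 23.4 ± 3.21 in R594C/+ and 28.5 ± 4.17 in R594C/R594C (SD, n = 4, 4 and 2). Xbp1 was at 1145 ± 144, 1241 ± 159 and 1407 ± 102 CPM in the same cells, and its log2 fold for R594C/R594C minus WT was 0.30 ± 0.12 (SE, adjusted p = 0.47). In follicular-like B cells Xbp1 was at 55.7 ± 3.95, 61.2 ± 5.58 and 53.9 ± 6.33 CPM. Neither gene passed 0.05 in any tested class. A point mutation leaves the level of a 3' tag free to stay as it was, and these tags do not tell spliced from unspliced Xbp1, so the levels check neither the genotype labels nor splicing. Transcripts of sex-linked genes, read as a sample check, put Xist, which is expressed from the inactive X chromosome, at 1364 CPM in WT replicate 2, at 1238 to 1380 in the R594C/+ replicates and at 1359 in R594C/R594C replicate 2. It was at 6.71 to 31.5 CPM in the others. By these transcripts WT was 3 males and 1 female, R594C/+ was 4 females, and R594C/R594C was 1 of each, so R594C/+ minus WT is nearly the same contrast as sex.

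The share of each cell type was compared next. Follicular-like B cells, the recirculating B cells of the spleen, made up 35.2% ± 2.9 of cells in WT, 31.3% ± 2.6 in R594C/+ and 40.2% ± 7 in R594C/R594C (SD, n = 4, 4 and 2). Marginal zone-like B cells, which face the blood, made up 6.5% ± 0.82, 7.83% ± 3.3 and 4.92% ± 0.095, and antibody-secreting plasma cell-like cells 1.93% ± 0.54, 2.83% ± 0.85 and 1.14% ± 0.1. B1-like cells were at 4.6% ± 1.9, 6.01% ± 1.8 and 3.35% ± 0.21, CD4 T-like cells at 8.69% ± 1.3, 5.57% ± 4.5 and 9.59% ± 5.1, and CD8 T-like cells at 6.61% ± 0.5, 5.63% ± 4.6 and 8.09% ± 3.1. The CD4 T-like and CD8 T-like classes are clusters 3 and 4 alone, both with Lef1 and Tcf7 among their top 10 genes. Clusters 7 and 15, each with 7 of 8 CD8 T markers, and cluster 9, with 7 of 8 CD4 T markers, stand outside them. In WT, R594C/+ and R594C/R594C, cluster 7 made up 6.12%, 4.07% and 3.2% and cluster 15 1.55%, 2.57% and 2.12%. Cluster 9 made up 4.41%, 5.94% and 2.77%. Shares of the CD4 T-like and CD8 T-like classes spread widely in the mutant genotypes. CD4 T-like cells ran from 1.46% in R594C/+ replicate 1 to 11.7% in replicate 3 and were at 5.98% and 13.2% in R594C/R594C replicates 1 and 2, and CD8 T-like cells ran from 0.713% to 11.3% in the same R594C/+ replicates and were at 5.91% and 10.3%. None of the 31 classes passed the two-sided exact permutation test of a trend with the number of R594C alleles (lowest adjusted p = 0.886; lowest adjusted p with an exact permutation of the F statistic 0.307). The smallest p of 2 against 4 replicates is 0.0667, so a difference between R594C/R594C and WT alone could not pass.

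**Figure D1:**
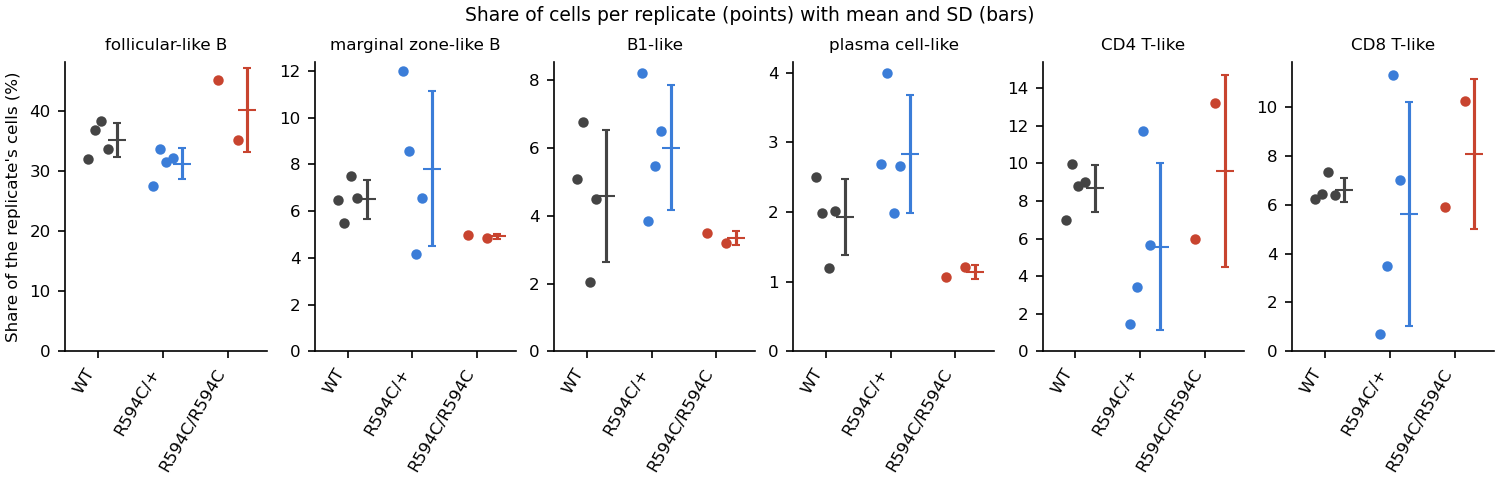
Share of each replicate's cells (%) in 6 classes, by genotype; points are replicates and bars the mean and SD. Plasma cell-like cells have means of 1.93% in WT, 2.83% in R594C/+ and 1.14% in R594C/R594C, and none of the 6 classes passed the test.

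Follicular-like B cells, the main B cell class, were compared between R594C/R594C and WT. The transcripts of ER chaperones, which fold secreted proteins, fell together. All 12 listed chaperones were lower, with a median log2 fold of -0.21 (adjusted p = 7.1e-09; 0.046 with an estimated correlation). Examples are the disulfide isomerase Pdia4 (-0.33 ± 0.08, from 84.1 ± 2.6 to 66.8 ± 1.51 CPM), the co-chaperone Dnajb11 (-0.31 ± 0.09) and calreticulin, Calr (-0.21 ± 0.08). None of the 12 passed 0.05 over all genes by edgeR, and 7 passed adjusted over the list alone. The genes of the interferon gamma response were lower in 17 of 18 (median -0.20, adjusted p = 7.5e-09; 0.094 with an estimated correlation), 1 of them past 0.05 over all genes and 2 adjusted over the list alone. That 1 gene was the transcription factor Irf1, which fell from 89.4 ± 6.38 to 66.5 ± 0.905 CPM (log2 fold -0.42).

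Single genes that fell were Socs3, a brake on cytokine signalling (-0.69, from 44.5 ± 6.2 to 27.6 ± 0.141 CPM, adjusted p = 0.0013), H2-K1, an MHC class I heavy chain (-0.25, from 1840 ± 53 to 1550 ± 26.2 CPM, adjusted p = 0.01), and Ccl5, a chemokine of effector T and NK cells (-1.22, adjusted p = 0.005). The IgG constant genes Ighg2c (-2.45, from 43.7 ± 4.23 to 7.98 ± 0.835 CPM, adjusted p = 3.3e-14) and Ighg2b (-1.21, adjusted p = 2.8e-05) also fell. The highest folds belonged to hemoglobin genes (Hbb-bs 1.78, Hba-a2 1.63, Hba-a1 1.59, Hbb-bt 1.24) and neutrophil genes (Camp 1.71, S100a9 1.20, S100a8 1.04). The ribosomal protein genes Rpl38, Rps28 and Rps29 rose by 0.23, 0.22 and 0.22. For each gene that lost its call, the replicates whose removal ended it (WT 4 is WT replicate 4), any other setting that did, and the highest adjusted p over all settings stand in parentheses. Calls were lost for Hbb-bs (margin rule, 0.998), Hba-a2 (margin rule, 0.998), Hba-a1 (margin rule, 0.998), Hbb-bt (margin rule, 0.998) and Rpl38 (R594C/R594C 1 and 2, no filter, 0.25). Others were Rps28 (WT 4, R594C/R594C 1 and 2, no filter, 0.28), Ccl5 (R594C/R594C 1 and 2, doublets kept, 0.998), Irf1 (WT 1, 3 and 4, R594C/+ 2 and 3, R594C/R594C 1 and 2, WT classes, doublets kept, DESeq2, 0.33), H2-K1 (WT 4, R594C/R594C 1 and 2, no filter, 0.33) and Rps29 (R594C/R594C 2, 0.13). Under the margin rule for hashtags the fold of Hbb-bs stayed at 1.78, while Hbb-bs UMIs in R594C/+ replicate 1 went from 248 to 3607.

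In all, 13 genes rose and 7 fell of 10678 tested, 1 of them a receptor segment of 19 tested. The count was 13 without R594C/R594C replicate 1 and 12 without replicate 2. Over the fixed lists, 13 of 32 passed with the preset correlation and 3 with an estimated correlation (the chaperones, erythroid and neutrophil genes). The lower ones included XBP1s targets (45 of 55 lower, median -0.09, adjusted p = 4.6e-07; 0.088 with an estimated correlation), of which Pdia4 alone passed adjusted over the list alone. Lower too were immunoglobulin constant genes (3.9e-07; 0.062 with an estimated correlation), age-associated B genes (0.0011; 0.088), T cell genes (0.0015; 0.088), T cell activation (0.0091; 0.28), MHC class II (0.031; 0.44) and RIDD substrates (0.034; 0.24). The higher ones were erythroid genes (1.1e-59; 2.3e-05 with an estimated correlation), neutrophil genes (1.6e-21; 0.00037), immediate early genes (0.016; 0.68) and monocyte genes (0.037; 0.17). Leaving out R594C/R594C replicate 2 brought the number of lists from 13 to 7. It ended the calls of age-associated B (0.082), T cell activation (0.21), MHC class II (0.36), RIDD (0.073), immediate early (0.80) and monocyte genes (0.18). Without R594C/R594C replicate 1, T cell (0.17), RIDD (0.17) and monocyte genes (0.057) did not pass. Without WT replicate 1, MHC class II (0.14), RIDD (0.14), immediate early (0.83) and monocyte genes (0.13) did not pass, nor did monocyte genes without WT replicate 3 (0.14) or T cell activation without WT replicate 4 (0.072).

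The remaining lists did not pass in this comparison. Their adjusted p-values by camera were 0.098 for B cell genes, 0.12 for the germinal centre and regulatory T programmes, 0.23 for proliferation, 0.30 for ATF4 and CHOP targets and the marginal zone programme, 0.36 for glycolysis, 0.40 for B cell inhibitory receptors and T follicular helper genes, and 0.54 for mitochondrially encoded genes. They were 0.61 for type I interferon, B cell receptor activation and sex-linked genes, 0.88 for the plasma cell and naive T programmes, oxidative phosphorylation, cholesterol synthesis and ribosomal proteins, and 0.97 for NF-kB. Among ribosomal protein genes 5 rose over all genes and 0 fell by edgeR (8 and 3 adjusted over the list alone). Median, mean and test differed in sign for the marginal zone programme (median 0.01, mean -0.17), type I interferon (-0.04, 0.07), naive T (0.06, -0.01) and sex-linked genes (-0.24, 0.01), and the test of cholesterol synthesis pointed up with a median of -0.02.

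**Figure D2:**
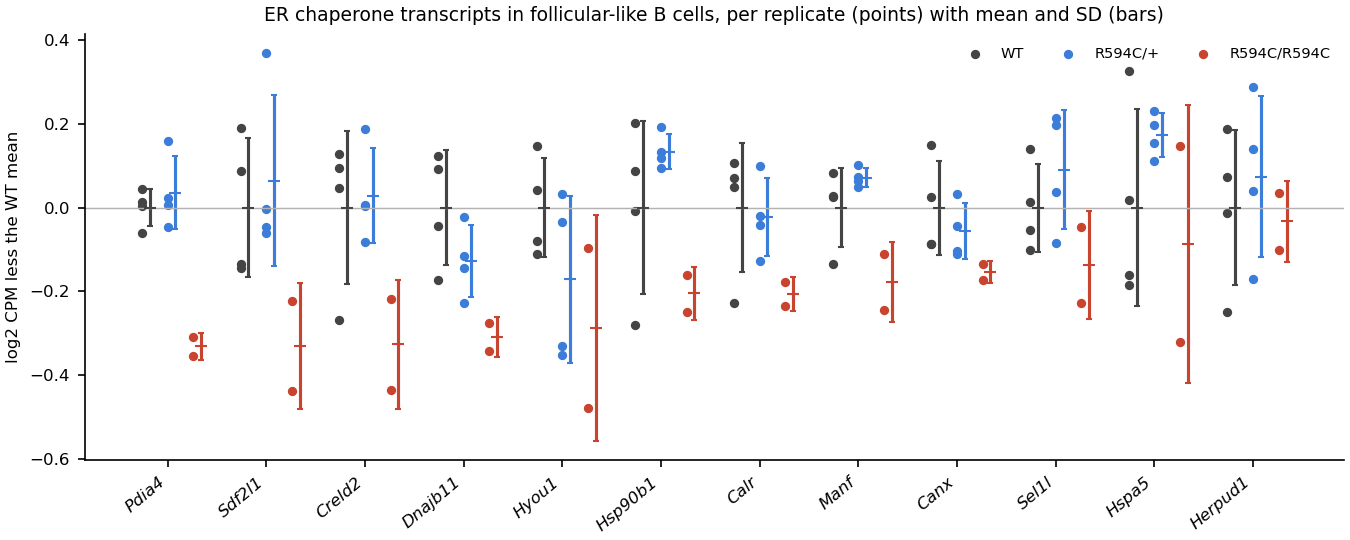
ER chaperone transcripts in follicular-like B cells, as log2 CPM less the WT mean, for each replicate (points) with mean and SD (bars). The R594C/R594C mean lies below the WT mean for all 12 genes, with Pdia4 at -0.33.

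The R594C/+ and WT replicates were compared in the same cells. Neutrophil genes rose (S100a8 2.25, S100a9 2.11, from 19.2 ± 4.43 to 83.4 ± 2.99 CPM, Camp 2.38), as did hemoglobin genes (Hba-a1 1.71, Hbb-bs 1.62, Hbb-bt 1.39) and the IgG genes Ighg1 (2.69, from 5.66 ± 2.98 to 35.6 ± 5.92 CPM) and Ighg2c (0.75). Proliferation genes were higher in 15 of 20 (adjusted p = 1.8e-05; 0.015 with an estimated correlation), 1 past 0.05 over all genes and 2 adjusted over the list alone, among them Birc5, which acts in cell division (1.66 ± 0.33). The mitochondrially encoded genes mt-Atp6 (-0.59, from 122 ± 4.42 to 81.1 ± 8.43 CPM) and mt-Co3 (-0.53) and the membrane protein gene Myadm (-0.53) fell, while Sec61g, a subunit of the ER translocon, rose by 0.55. The ribosomal protein genes Rps21, Rpl38 and Rpl39 rose by 0.14, 0.17 and 0.14.

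In all, 30 genes rose and 7 fell. With expressed sex in the fit 38 rose and 30 fell (68 in all), and by DESeq2 24 and 13. Calls were lost for Hba-a1 (margin rule, 0.58), Myadm (R594C/+ 2, sex, 0.057), mt-Co3 (WT 1 and 3, R594C/+ 2 and 3, 0.11), Sec61g (WT 2 and 3, R594C/+ 2 and 4, 0.094) and Birc5 (WT 3, R594C/+ 3, 0.083). Others were Rps21 (WT 1, 2, 3 and 4, R594C/+ 2, 3 and 4, sex, WT classes, DESeq2, no filter, 0.54), Rpl38 (WT 2 and 3, R594C/+ 1, 2, 3 and 4, R594C/R594C 1, WT classes, DESeq2, no filter, 0.32), Rpl39 (WT 1, 2, 3 and 4, R594C/+ 1, 2, 3 and 4, R594C/R594C 1, WT classes, DESeq2, no filter, 0.58), Hbb-bs (margin rule, 0.55) and Hbb-bt (margin rule, 0.6). ER chaperones and XBP1s targets did not pass here (both 0.66). Lists that rose were neutrophil (2.7e-64; 3.2e-05 with an estimated correlation) and erythroid genes (1.2e-47; 3.2e-05), immediate early genes (5.5e-06; 0.42), immunoglobulin constant genes (1.8e-05; 0.086), ribosomal proteins and monocyte genes (both 0.0045; 0.54 and 0.086), type I interferon (0.0052; 0.42) and the plasma cell programme (0.0091; 0.086). Lists that fell were mitochondrially encoded genes (2.3e-07; 0.086 with an estimated correlation), cholesterol synthesis (1.8e-05; 0.31) and sex-linked genes (1.8e-05; 0.076). Type I interferon and the plasma cell programme did not pass without WT replicate 1 (0.11 and 0.083) or R594C/+ replicate 4 (0.38 and 0.062).

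In follicular-like B cells, R594C/R594C minus R594C/+ compared 2 mutated copies with 1. ER chaperones were again all lower in R594C/R594C (12 of 12, median -0.23, adjusted p = 2.8e-08; 0.058 with an estimated correlation), 1 past 0.05 over all genes (Pdia4, -0.36 ± 0.08, adjusted p = 0.03) and 5 adjusted over the list alone. All 18 interferon gamma genes were lower (adjusted p = 1e-09; 0.094 with an estimated correlation), with Irf1 at -0.41. IgG genes moved apart: Ighg1 (-3.28), Ighg2c (-3.19) and Ighg2b (-1.64) were lower and Ighg3 was higher (0.80, 85.7 ± 0.495 against 48.8 ± 6.02 CPM). Myadm (0.94) and mt-Atp6 (0.48) were higher, and Slpi, a protease inhibitor of neutrophils and epithelia (-1.61), S100a8 (-1.21), Lcn2 (-1.52), Ccl5 (-1.01) and Ighm (-0.27) lower.

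In all, 16 genes were higher and 46 lower. The count was 28 without R594C/+ replicate 2, 16 without R594C/R594C replicate 1 and 37 without replicate 2, and 137 with expressed sex in the fit (55 higher and 82 lower). Calls were lost for Ighg3 (margin rule, 0.21), C130089K02Rik (R594C/+ 2, R594C/R594C 1, sex, 0.43), Pdia4 (R594C/+ 1, 2 and 4, R594C/R594C 1 and 2, DESeq2, 0.32), Irf1 (R594C/+ 2, 3 and 4, R594C/R594C 1 and 2, WT classes, doublets kept, thinned, DESeq2, 0.28) and Ffar2 (WT 1, 3 and 4, R594C/+ 1, R594C/R594C 1 and 2, margin rule, WT classes, thinned, 0.34). Others were Basp1 (R594C/+ 1, 2, 3 and 4, R594C/R594C 1 and 2, sex, doublets kept, DESeq2, 0.41), Ccl5 (R594C/+ 1 and 2, R594C/R594C 1 and 2, doublets kept, 0.7), Rps29 (R594C/+ 2, R594C/R594C 1 and 2, doublets kept, DESeq2, no filter, 0.26), Rps9 (R594C/+ 2 and 3, R594C/R594C 1 and 2, DESeq2, no filter, 0.42) and Rps14 (WT 4, R594C/+ 2 and 3, R594C/R594C 1 and 2, DESeq2, no filter, 0.57). Others were Lcn2 (R594C/R594C 1 and 2, 0.11) and Ighm (R594C/R594C 2, doublets kept, 0.53). Of the lists, 16 passed and 2 did with an estimated correlation, immunoglobulin constant genes (lower, 6e-12; 0.025) and neutrophil genes (lower, 2.5e-24; 0.0013). XBP1s targets were lower in 41 of 55 (0.00013; 0.12 with an estimated correlation), and mitochondrially encoded genes (7e-08; 0.094) and cholesterol synthesis (9.1e-05; 0.27) were higher. Without R594C/R594C replicate 2 the number of lists was 10, and cholesterol synthesis did not pass (0.24). The remaining genes named by the list rule, Ffar2 (-2.91), Basp1 (-1.25), Rps29 (0.17), Rps9 (-0.17), Rps14 (-0.15) and the long noncoding gene C130089K02Rik (0.77), had adjusted p-values of 0.041, 0.048, 0.019, 0.027, 0.028 and 0.016.

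Marginal zone-like B cells answer blood-borne antigens. In R594C/R594C minus WT the ribosomal protein genes Rps28 (0.39), Rpl38 (0.34) and Rps29 (0.34, from 4786 ± 123 to 6050 ± 147 CPM) rose, and 26 of 33 listed ribosomal genes were higher (adjusted p = 0.00057; 0.63 with an estimated correlation; 0.067 without R594C/R594C replicate 1), 7 past 0.05 over all genes and 10 adjusted over the list alone. Mitochondrially encoded genes were higher in 10 of 11 (adjusted p = 0.029, and 0.63 with an estimated correlation), a call that ended without WT 2 or 3 or R594C/R594C 1 or 2 (up to 0.17). T cell genes were lower in 4 of 5 (0.008 and 0.29), which ended without WT 1 or R594C/R594C 1 or 2 (up to 0.25). Erythroid genes (1.8e-25 and 0.00052) and neutrophil genes (0.00014 and 0.044) were higher. Hemoglobin genes rose (Hbb-bs 1.69, Hba-a1 1.64, Hbb-bt 1.5), as did the predicted genes Gm28438 (0.57) and Gm45153 (0.44) and the B cell factor Ebf1 (0.25). Ighg2c (-3.13), Ighg2b (-1.12) and Vim, the filament protein vimentin (-1.0, from 45.1 ± 7.44 to 22.6 ± 3.74 CPM), fell. In R594C/+ minus WT, S100a8 (2.51), S100a9 (1.85), Camp (3.24), Hba-a1 (2.05), Hbb-bs (1.77), Hbb-bt (1.76) and Ighg1 (1.73) rose, with Prdm1, the regulator of plasma cell formation (1.22 ± 0.28), Cd69, an early activation marker (0.40), Rps21 (0.22), Rpl38 (0.23) and Rpl32 (0.18). Vim (-0.97), mt-Atp6 (-0.66), Cmah (-0.55) and Ighd, the IgD constant region (-0.49), fell. There mitochondrially encoded genes were lower in 9 of 11 (adjusted p = 1.6e-05, and 0.21 with an estimated correlation), and erythroid (8.7e-29 and 0.00012) and neutrophil genes (1.8e-40 and 7.7e-05) were higher.

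For R594C/R594C minus WT, 16 genes rose and 3 fell of 8866 and 11 and 9 passed without R594C/R594C replicate 1 and 2. Calls were lost for Hba-a1 (R594C/R594C 2, 0.079), Hbb-bt (R594C/R594C 2, 0.21), Gm28438 (WT 2, R594C/R594C 1 and 2, doublets kept, DESeq2, 0.26), Gm45153 (WT 1 and 4, R594C/+ 4, R594C/R594C 1 and 2, sex, doublets kept, DESeq2, 0.44) and Rpl38 (R594C/R594C 1, 0.053). Others were Ighg2b (R594C/R594C 1, 0.26), Vim (WT 3, R594C/R594C 1 and 2, margin rule, WT classes, doublets kept, DESeq2, 0.96) and Ebf1 (WT 1, 2 and 3, R594C/+ 4, R594C/R594C 1 and 2, sex, WT classes, doublets kept, DESeq2, no filter, 0.59). For R594C/+ minus WT 30 rose and 9 fell. The count was 24, 20, 24 and 23 without WT replicates 1 and 3 and R594C/+ replicates 3 and 4, and 23 with expressed sex in the fit (13 higher and 10 lower), and DESeq2 gave 12 higher and 1 lower. For R594C/+, calls were lost for S100a8 (doublets kept, 0.28), S100a9 (doublets kept, 0.59), Vim (WT classes, doublets kept, 0.58), mt-Atp6 (sex, 0.14) and Cmah (WT 1, 2 and 3, R594C/+ 1, 3 and 4, sex, doublets kept, 0.32). Others were Cd69 (sex, 0.27), Prdm1 (WT 1, 2, 3 and 4, R594C/+ 1 and 3, sex, margin rule, WT classes, thinned, 0.31), Ighd (WT 1, 2 and 3, R594C/+ 3, sex, 0.34), Rps21 (sex, 0.14) and Rpl32 (sex, 0.21). Rpl38 was another (sex, 0.11). The chaperones were lower in 9 of 12 in R594C/R594C (adjusted p = 0.023; 0.29 with an estimated correlation; 0.19 and 0.051 without R594C/R594C replicates 1 and 2, 0.20 without WT replicate 4) and higher in 10 of 12 in R594C/+ (0.004; 0.21 with an estimated correlation). In R594C/+ the plasma cell programme was higher in 10 of 10 (0.00074; 0.21 with an estimated correlation), with 1 past 0.05 over all genes and 3 adjusted over the list alone.

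B1-like cells, innate-like B cells that make natural antibodies, had the most changed genes between R594C/R594C and WT among all classes, and were added as a tested class after those counts had been seen. The name rests on 3 of 7 B1 markers (Bhlhe41, Zbtb32 and Plscr1, not Cd5) beside 2 of 7 age-associated B markers (Fcrl5 and Zeb2), and on 3 of 7 of each, Fgl2 being the added one, when WT cells alone were clustered. The MHC class II genes, which present antigen to CD4 T cells, were lower in 12 of 12 (median -0.34, adjusted p = 4.8e-11; 0.13 with an estimated correlation), 4 past 0.05 over all genes and 10 adjusted over the list alone. H2-Ab1 fell from 4606 ± 435 to 3645 ± 122 CPM (-0.34), H2-Eb1 by 0.33 and Cd74 by 0.27 on the log2 scale. Mitochondrially encoded genes were higher in 9 of 11 (adjusted p = 0.016, and 0.52 with an estimated correlation), a call that ended without WT 4 (0.13) or R594C/R594C 2 (0.25). Ribosomal protein genes were higher in 22 of 33 (0.029 and 0.76), which ended without WT 3 or 4 or R594C/R594C 2 (up to 0.47). Erythroid (1.9e-12 and 0.0038) and neutrophil genes (6e-05 and 0.13) were higher, in R594C/+ too (7e-18 and 0.0012, 1.3e-26 and 0.0033). The inhibitory IgG receptor Fcgr2b fell from 137 ± 30.7 to 71.7 ± 0.347 CPM (-0.95, adjusted p = 0.0036) and the inhibitory receptor Lilrb4a from 25.6 ± 1.35 to 7.07 ± 3.27 CPM (-1.85). The age-associated B list was lower in 10 of 11 (4.9e-07; 0.049 with an estimated correlation), with the integrin gene Itgam at -2.03. App (-1.44) and Pitpnc1 (-1.09) fell. Hba-a1 (1.97), Hbb-bs (1.80), Hbb-bt (1.48), S100a9 (1.33), Izumo1r (2.20), the survival kinase Pim1 (0.48), Rps28 (0.34) and Rpl38 (0.33) rose. In R594C/+ 10 genes rose and 0 fell by edgeR (403 at an unadjusted p under 0.05; 11 changed by DESeq2), among them S100a8 (2.37), S100a9 (2.05), Hbb-bt (1.77), Hba-a1 (1.68), Hbb-bs (1.42), Jchain, which links IgM (0.80), and Dusp1 (0.56).

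The R594C/R594C count was 17 higher and 23 lower of 9025, and by DESeq2 10 and 31. It was 80, 68 and 10 without WT replicates 2, 3 and 4, 26 without R594C/+ replicate 3, and 4 and 14 without R594C/R594C replicates 1 and 2. Calls were lost for Hbb-bt (WT 2 and 4, R594C/+ 3, R594C/R594C 1 and 2, margin rule, WT classes, doublets kept, thinned, 0.53), Lilrb4a (R594C/R594C 1, 0.33), App (WT 4, R594C/+ 1 and 3, R594C/R594C 1 and 2, margin rule, WT classes, thinned, 0.45), Pitpnc1 (WT 4, R594C/R594C 1, 0.53) and H2-Eb1 (WT 1 and 4, R594C/R594C 1 and 2, sex, WT classes, 0.5). Others were H2-Ab1 (WT 1 and 4, R594C/R594C 1 and 2, sex, 0.5), Cd74 (WT 1 and 4, R594C/R594C 1 and 2, sex, DESeq2, no filter, 0.66), Itgam (WT 2 and 4, R594C/R594C 1 and 2, doublets kept, thinned, 0.45), Pim1 (WT 1 and 4, R594C/R594C 1 and 2, doublets kept, 0.31) and Fcgr2b (R594C/R594C 1 and 2, 0.17). Others were Izumo1r (R594C/R594C 1, doublets kept, 0.76), Rps28 (WT 4, R594C/R594C 1 and 2, sex, 0.56), Rpl38 (WT 4, R594C/+ 1, 3 and 4, R594C/R594C 1 and 2, sex, doublets kept, no filter, 0.42) and S100a9 (WT 2, R594C/R594C 1 and 2, thinned, 0.93). With doublets kept, S100a9 turned to -0.79 here and Jchain to -0.99 in R594C/+. In R594C/+, they were lost for S100a8 (doublets kept, 0.999), S100a9 (doublets kept, 0.999), Hbb-bt (WT 2, doublets kept, 0.19), Dusp1 (WT 1 and 2, R594C/+ 3 and 4, 0.16) and Jchain (WT 1, 2 and 3, R594C/+ 3, sex, margin rule, 0.998). XBP1s targets (38 of 55 lower, adjusted p = 0.0034; 0.13 with an estimated correlation; 0.24 without R594C/R594C replicate 1) and chaperones (12 of 12 lower, 0.0023; 0.34 with an estimated correlation; 0.25 without R594C/R594C replicate 1 and 0.078 without WT replicate 2) were lower too. The change differed from that in follicular-like B cells for 8 genes (edgeR interaction), and Fcgr2b (difference -0.91) was among them.

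Plasma cell-like cells secrete antibody and hold the most Xbp1. Between R594C/R594C and WT the XBP1s targets were lower in 46 of 55 (median -0.24, adjusted p = 2.8e-09; 0.17 with an estimated correlation), 2 past 0.05 over all genes and 11 adjusted over the list alone. The 2 were Edem2, which marks misfolded proteins for degradation (-0.57 ± 0.12, from 276 ± 20.7 to 185 ± 31.8 CPM), and Dad1, a subunit of the enzyme that adds sugars to new proteins (-0.52 ± 0.11, from 363 ± 23.7 to 254 ± 18.3 CPM). Dnajb9, an ER co-chaperone, was at -0.53 ± 0.12 (adjusted p = 0.085). The list of ER chaperones under ATF6 did not pass (6 higher, 6 lower; 0.99). Isg20, an interferon-induced nuclease, fell from 188 ± 33.1 to 91.4 ± 8.3 CPM (-1.04 ± 0.15, adjusted p = 0.00086), and its fall differed from follicular-like B cells by -1.19 in the interaction test. Insig1, a brake on sterol synthesis (-1.56), Cyp4f18 (-1.42) and Smim14 (-1.23) fell, and Hbb-bs rose by 2.10. In R594C/+ the XBP1s targets did not pass (0.50), S100a8 (4.51), S100a9 (2.84), Camp (2.76), Hbb-bt (2.6), Hbb-bs (1.95) and the adhesion gene Epcam (0.68) rose, and 0 genes fell by edgeR (372 at an unadjusted p under 0.05; 7 changed by DESeq2).

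The R594C/R594C count was 1 higher and 8 lower of 6797, and by DESeq2 5 and 14 (19 in all). It was 27 and 1 without WT replicates 2 and 4, 3 and 4 without R594C/+ replicates 2 and 3, and 5 without R594C/R594C replicate 2. At least 1 setting ended the calls of Hbb-bs (WT 1 and 4, R594C/+ 2, R594C/R594C 1 and 2, WT classes, 0.22), Insig1 (WT 1, 3 and 4, R594C/+ 2 and 3, R594C/R594C 1 and 2, sex, margin rule, 0.38), Cyp4f18 (WT 4, R594C/R594C 1 and 2, 0.22), Smim14 (WT 1, 3 and 4, R594C/+ 1, 2 and 3, R594C/R594C 2, sex, doublets kept, 0.48), Edem2 (WT 3 and 4, R594C/+ 1, 2 and 3, R594C/R594C 1, 0.4) and Dad1 (WT 3 and 4, R594C/+ 1, 2 and 3, R594C/R594C 1 and 2, sex, 0.32). The XBP1s list kept its call with each replicate left out (up to 0.0053). Also called were naive T genes (6 of 6 higher, 2.9e-05; 0.052 with an estimated correlation), ribosomal proteins (33 of 33 higher, 0.00065; 0.64; 0.067 without R594C/R594C replicate 2) and mitochondrially encoded genes (10 of 11 higher, 0.00065; 0.50). Erythroid (adjusted p = 1.8e-06, and 0.052 with an estimated correlation) and neutrophil genes (0.0072 and 0.20) were higher, in R594C/+ too (4.1e-15 and 0.0028, 1.6e-29 and 0.001). T cell genes were lower in R594C/+ in 3 of 3 (0.032 and 0.31), which ended without WT 4 or R594C/+ 1, 2 or 4 (up to 0.35). In R594C/+, 8 genes rose (4 without WT replicate 4, 3 without R594C/+ replicate 2, and 2 with expressed sex in the fit). Calls were lost there for Hbb-bs (WT 1 and 4, R594C/+ 2, sex, WT classes, 0.98), Epcam (WT 1 and 4, R594C/+ 1, 2 and 4, sex, margin rule, WT classes, doublets kept, DESeq2, 0.75), Hbb-bt (sex, WT classes, 0.98), S100a8 (sex, 0.2) and Camp (WT 1, 2 and 4, R594C/+ 1, 2 and 3, sex, thinned, DESeq2, 0.43).

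**Figure D3:**
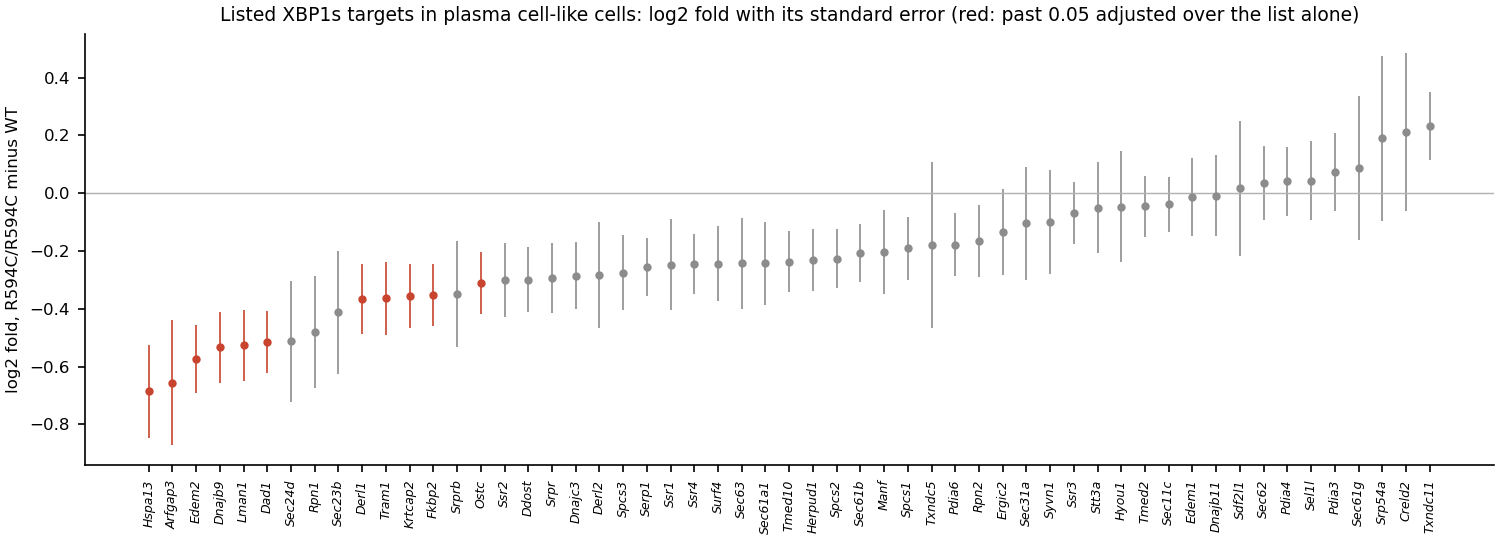
Listed XBP1s targets in plasma cell-like cells, as the log2 fold for R594C/R594C minus WT with its standard error, 1 point per gene; red marks the 11 genes past 0.05 adjusted over the list alone. The points lie below 0 for 46 of 55 genes, with Edem2 at -0.57.

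T cells do not make immunoglobulin or hemoglobin, and transcripts of both changed in them. In CD4 T-like cells, R594C/R594C minus WT raised Hbb-bs (1.86), Hba-a1 (1.73), Hba-a2 (1.53), Hbb-bt (1.49), S100a9 (1.27), Ighg3 (0.95) and Igha (0.79) and lowered Ighg2c (-2.52, from 37.6 ± 8.6 to 6.36 ± 0.278 CPM) and Ccl5 (-1.10). R594C/+ minus WT raised S100a8 (2.34), S100a9 (2.33), Camp (3.22), Hba-a1 (2.04), Hbb-bs (1.78), Hbb-bt (1.69), Ighg1 (2.82), Ighg2c (0.89) and Ighm (0.61), and lowered Myl12b, a myosin light chain (-0.51), and Rps27rt (-0.49) and Gm11478 (-0.43), which may share reads with near-identical copies. In CD8 T-like cells R594C/R594C minus WT raised Hbb-bs (2.00), Hbb-bt (1.88), Hba-a2 (1.67), Hba-a1 (1.19) and Igha (1.01) and lowered Ighg2c (-2.39), Ccl5 (-1.15), the MHC class II genes Cd74 (-0.72, from 234 ± 16 to 141 ± 2.62 CPM) and H2-Aa (-0.72), and Igkc (-0.64). The list of B cell genes was lower there in 11 of 11 (4.7e-22; 0.005 with an estimated correlation). R594C/+ minus WT raised S100a8 (2.11), Hbb-bt (1.96), S100a9 (1.74), Hbb-bs (1.68), Hba-a1 (1.44), Ighg1 (2.49), Jchain (0.80) and Igkc (0.76) and lowered Cd79a (-0.98), H2-Aa (-0.73) and Cd74 (-0.70).

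The counts in CD4 T-like cells were 7 higher and 2 lower of 7947 for R594C/R594C (16 without WT replicate 2) and 12 and 4 for R594C/+ (10 without R594C/+ replicate 2), and in CD8 T-like cells 5 and 5 of 7942 (21 without WT replicate 2, 6 without R594C/R594C replicate 2) and 12 and 3 (9 and 8 with expressed sex in the fit). With doublets kept, Ccl5 and Cd74 in CD8 T-like cells turned to 0.11 and 0.02 for R594C/R594C, and Cd74 to 0.03 for R594C/+. In CD4 T-like cells, calls were lost in R594C/R594C for Hba-a2 (WT 1, R594C/R594C 1, DESeq2, 0.56), Ccl5 (WT 4, R594C/R594C 2, WT classes, thinned, DESeq2, 1), Ighg3 (DESeq2, 0.2), Igha (WT 1, 2 and 4, R594C/+ 1, 2 and 4, R594C/R594C 1 and 2, doublets kept, DESeq2, 1) and Hbb-bt (R594C/R594C 2, 0.051). S100a9 was another (WT 1, R594C/R594C 1, DESeq2, 0.24). In R594C/+ they were lost for Myl12b (WT 4, R594C/+ 2 and 3, sex, DESeq2, 0.54), Rps27rt (WT 1, 3 and 4, R594C/+ 1, 2 and 3, sex, WT classes, DESeq2, 0.36), Gm11478 (WT 1 and 4, R594C/+ 1, 2, 3 and 4, sex, DESeq2, no filter, 0.25), Ighm (WT classes, doublets kept, 0.73) and Ighg2c (WT 2, R594C/+ 3, DESeq2, 0.61). In CD8 T-like cells, they were lost in R594C/R594C for Hbb-bt (R594C/R594C 2, 0.24), Hba-a1 (WT 1, 2 and 3, R594C/R594C 2, sex, DESeq2, 1), Ccl5 (margin rule, WT classes, 1), H2-Aa (R594C/R594C 2, doublets kept, DESeq2, 1) and Igha (R594C/R594C 2, DESeq2, 0.25). Others were Igkc (WT 3, R594C/R594C 1, doublets kept, 0.087) and Hba-a2 (WT 1 and 3, R594C/R594C 2, DESeq2, 1). In R594C/+ there, they were lost for Cd79a (WT 1, 2 and 3, R594C/+ 3 and 4, margin rule, doublets kept, thinned, DESeq2, 1), H2-Aa (R594C/+ 4, margin rule, doublets kept, DESeq2, 1) and Hba-a1 (sex, 0.055).

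The immunoglobulin constant list was higher in R594C/+ CD4 T-like cells (camera adjusted p = 0.00067; 0.078 with an estimated correlation; 0.066 without R594C/+ replicate 3) with a median of -0.08 and a mean of 0.30. Interferon gamma genes were lower in R594C/R594C in 15 of 15 in CD4 T-like (0.00012; 0.32 with an estimated correlation; 0.89 without R594C/R594C replicate 2) and 16 of 16 in CD8 T-like cells (5.4e-07; 0.18; 0.45 without R594C/R594C replicate 2), and type I interferon genes in 17 of 23 (0.00066; 0.12; 0.36 without R594C/R594C replicate 2) and 19 of 21 (1.4e-06; 0.18). XBP1s targets were lower in R594C/R594C in 37 of 53 in CD4 T-like cells (adjusted p = 0.025, and 0.079 with an estimated correlation) and in 34 of 53 in CD8 T-like cells (0.042 and 0.16). ER chaperones were lower in 10 of 12 in CD4 T-like cells (0.04 and 0.45). By edgeR 0 members of these lists passed adjusted over the list alone. The XBP1s call ended in CD4 T-like cells without WT 1, 2 or 4 or R594C/R594C 1 or 2 (up to 0.103). In CD8 T-like cells it ended without WT 1, 3 or 4 or R594C/R594C 1 (up to 0.32). The chaperone call ended without WT 2 or 4 or R594C/R594C 1 or 2 (up to 0.43). MHC class II genes were lower in 9 of 9 in CD4 T-like cells (8.6e-06 and 0.079) and in 8 of 9 in CD8 T-like cells (1.2e-08 and 0.034). In CD8 T-like cells of R594C/+ they were lower in 9 of 9 (1.5e-08 and 0.026). Immunoglobulin constant genes were lower in R594C/R594C in 8 of 11 in CD4 T-like cells (0.0037 and 0.079) and in CD8 T-like cells (3.7e-06 and 0.15). The CD4 call ended without WT 3 or R594C/R594C 2 (up to 0.098). In CD4 T-like cells of R594C/R594C B cell genes were lower in 11 of 11 (2.7e-08 and 0.078), the germinal centre programme in 4 of 4 (0.0058 and 0.079) and the marginal zone programme in 7 of 7 (0.049 and 0.17). T cell activation genes were lower in 5 of 8 (0.0046 and 0.22) and oxidative phosphorylation genes in 28 of 34 (0.012 and 0.49). Left-out replicates ended these calls except that of B cell genes. The germinal centre call ended without WT 2 or R594C/R594C 1 or 2 (up to 0.27), and the marginal zone call without WT 1, 3 or 4 or R594C/R594C 1 or 2 (up to 0.19). The activation call ended without WT 2 or R594C/R594C 2 (up to 0.078), and that of oxidative phosphorylation without WT 1 or 4 or R594C/R594C 2 (up to 0.58). Mitochondrially encoded genes were higher in CD8 T-like cells of R594C/R594C in 8 of 11 (0.029 and 0.43), which ended without WT 2 or 4 or R594C/R594C 1 or 2 (up to 0.20), and lower in CD4 T-like cells of R594C/+ in 9 of 11 (0.0026 and 0.43), which ended without R594C/+ 1 (0.076).

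Conventional dendritic-like cells, which take up and present antigen, were few. The class is cluster 27 alone, with 7 of 9 markers of type 1 conventional dendritic cells (cDC1) and 2 of 9 of type 2 (cDC2). Cluster 17, with 4 of 9 cDC2 markers, stands outside it, and the lists were not tested there. The results of this class therefore concern cDC1-like cells. The targets of ATF4 and CHOP, transcription factors of the integrated stress response, were higher in R594C/R594C than in WT in 12 of 12 (median 0.78, adjusted p = 2.3e-11; 0.0059 with an estimated correlation; up to 7e-06 with a replicate left out). None passed over all genes by edgeR and 6 passed adjusted over the list alone. Examples are the serine synthesis enzyme Phgdh (2.98 ± 0.58, from 9.21 ± 6.27 to 85.8 ± 32.4 CPM), the folate enzyme Mthfd2 (1.09 ± 0.26, from 108 ± 35.1 to 232 ± 8.63 CPM) and asparagine synthetase, Asns (49.6 ± 2.5 against 1.1 ± 2.2 CPM). Transcripts of other cell types moved too. Hbb-bs was at 0.982 UMIs per cell in R594C/R594C, 0.417 in R594C/+ and 0.312 in WT, and in R594C/R594C cells with 1 to 4 UMIs of a gene held 52.7% of its Hbb-bs, 33.3% of its Hbb-bt and 21.2% of its S100a9 UMIs. B cell genes were lower in R594C/R594C in 10 of 11 (adjusted p = 1e-04, and 0.36 with an estimated correlation), which ended without R594C/R594C replicate 1 (0.068). Proliferation genes were higher in 18 of 18 (4.4e-17; 0.17 with an estimated correlation) and ER chaperones in 12 of 12 (0.00036; 0.41; 0.15 without R594C/R594C replicate 2), with BiP, Hspa5, at 0.87 ± 0.18 (adjusted p = 0.18). By edgeR 0 of 4197 genes passed for R594C/R594C (218 at an unadjusted p under 0.05; 0 by DESeq2) and 0 for R594C/+ (255; 0 by DESeq2). Single replicates moved this. For R594C/R594C, 8 genes passed without R594C/+ replicate 3, 3 without R594C/R594C replicate 2, 2 without R594C/+ replicate 2, and 1 each without WT replicate 2, R594C/+ replicate 1 or R594C/R594C replicate 1. For R594C/+, 8 passed without R594C/+ replicate 3 and 1 without replicate 2. In R594C/+ minus WT, proliferation (9.3e-10; 0.53 with an estimated correlation) and oxidative phosphorylation genes (9.3e-05; 0.64) were higher and B cell receptor activation (2.1e-06; 0.33) and NF-kB genes (0.00041; 0.33) lower.

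The transcripts of other cells were also read as shares of cells with a UMI. Hbb-bs was found in 9.85%, 25.6% and 26.2% of follicular-like B cells in WT, R594C/+ and R594C/R594C (median depth 2790, 2551 and 2412 UMIs) and in 9.07%, 25.1% and 26.3% of CD4 T-like cells (3487, 3019.5 and 3071 UMIs), and both types lack hemoglobin. Ighg2c was found in 9.62%, 16.8% and 1.93% of follicular-like B cells and in 10.2%, 17.9% and 1.86% of CD4 T-like cells, which do not make it, so the follicular-like values are at the level of background. S100a9 was found in 4.48%, 18.8% and 9.77% of follicular-like B cells. Over whole captures the plasma cell-like cells held 52569, 90274 and 5510 Ighg2c UMIs, erythroid-like cells numbered 34, 124 and 87, and neutrophil-like cells 95, 180 and 160.

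**Figure D4:**
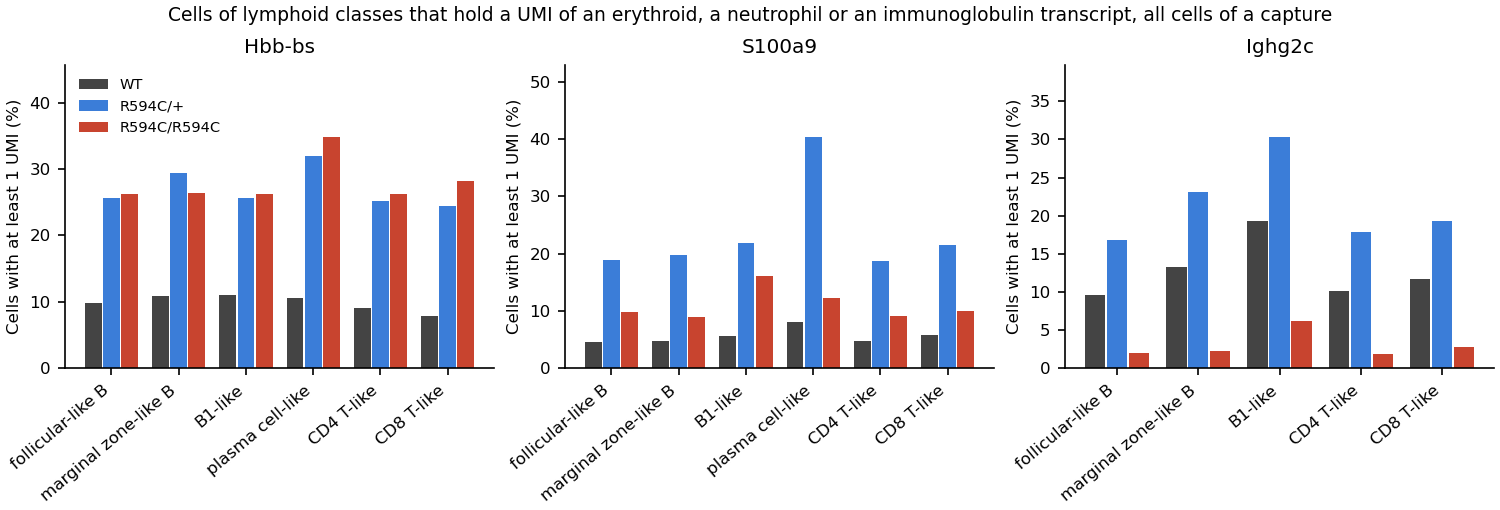
Percent of cells of lymphoid classes with at least 1 UMI of Hbb-bs, S100a9 or Ighg2c, by genotype, over all cells of a capture; plasma cell-like cells are left out of the Ighg2c panel. Hbb-bs goes from 9.85% to 26.2% between WT and R594C/R594C in follicular-like B cells and from 9.07% to 26.3% in CD4 T-like cells.

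Antibody tags were compared to ask about surface proteins. In follicular-like B cells the highest in R594C/R594C over WT were CD24, a B cell surface glycoprotein (log2 fold 1.85), Ly6G_Ly6C (1.82), the complement receptors CD21_CD35 (1.76), MHC class II IA_IE (1.76) and CD371 (1.74), and the lowest CD204 (-3.14), RORg (-2.64), Folate (-2.60), CD146 (-2.55) and ReceptorD4 (-2.53). The isotype controls, antibodies with no target on these cells, changed too: all 10 passed, 9 lower and 1 higher (median -1.10). Of 170 antibodies 60 were higher and 79 lower, and with RLE scaling 68 and 71. The 33 antibodies above the highest isotype control had a median of 1.61, and 31 of them were higher and 0 lower by edgeR; the other 137 had a median of -0.78. When only those 33 were scaled and tested, 4 passed, all lower, and CD24, CD21_CD35 and IA_IE were at 0.23, 0.22 and 0.11. In R594C/+ minus WT 39 were higher and 78 lower (2 and 78 with expressed sex in the fit), 9 isotype controls among them, led by Ly6G_Ly6C (1.49), Ly6A_Ly6E (0.86), CD150 (0.78), CD370 (0.75) and IA_IE (0.74) and, lower, CD64 (-1.16), CD304 (-1.09), CD204 (-1.01), CD200R3 (-1.0) and CD195 (-1.0). RLE scaling gave 57 higher and 62 lower, and 1 passed, lower, among the tags above the isotype controls.

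In marginal zone-like B cells 38 of 168 tags were higher and 71 lower in R594C/R594C (59 and 50 with RLE scaling; 8 of 10 isotype controls changed), led by CD1d (1.09), Ly6A_Ly6E (1.02), CD371 (1.00), CD24 (1.00) and IA_IE (0.99) and, lower, CD146 (-3.19), IL33Ra (-3.13), TCRb5 (-2.98), CD204 (-2.83) and an isotype control, IgG2b_Rat_k (-2.71). In R594C/+ 15 were higher and 56 lower (39 and 25 with RLE scaling), led by CD1d (0.58), CD274 (0.55), IA_IE (0.51), Ly6A_Ly6E (0.51) and CD45R_B220 (0.49) and, lower, ReceptorD4 (-1.64), TCRb5 (-1.34), RORg (-1.21), CD90 (-1.20) and CD152 (-1.19). With expressed sex in the fit 14 passed, 1 higher and 13 lower. In CD4 T-like cells 48 of 166 were higher and 81 lower in R594C/R594C (58 and 63 with RLE scaling; all 10 isotype controls changed), led by CD8b (1.84), CD8a (1.54), CD90_A0075 (1.48), TCRb (1.46) and CD5 (1.40) and, lower, IgG2b_Rat_k (-4.73), RORg (-4.06), Folate (-3.99), CD23 (-3.82) and CD200R3 (-3.39). In R594C/+ 28 were higher and 41 lower, led by CD5 (0.88), CD278_A0171 (0.84), CD150 (0.83), CD49d (0.80) and CD11a (0.74). The lowest were ReceptorD4 (-1.50), XCR1 (-1.29), CD90 (-1.16, against 0.62 for the more abundant CD90_A0075), IgG_Hamster (-1.11) and CD366 (-1.08). The R594C/+ count was 43 without WT replicate 2, 45 without R594C/+ replicate 3 and 41 with expressed sex (11 higher and 30 lower). RLE scaling gave 32 and 17. Above the isotype controls 0 passed in marginal zone-like and CD4 T-like cells for R594C/R594C by edgeR (7 and 5 at an unadjusted p under 0.05), and 1 and 0 for R594C/+ (5 and 4 unadjusted). DESeq2 was not run on tags. The CD23 tag was found on 12.4%, 7.36% and 3.21% of follicular-like, marginal zone-like and CD4 T-like cells, too few for a surface gate.

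**Figure D5:**
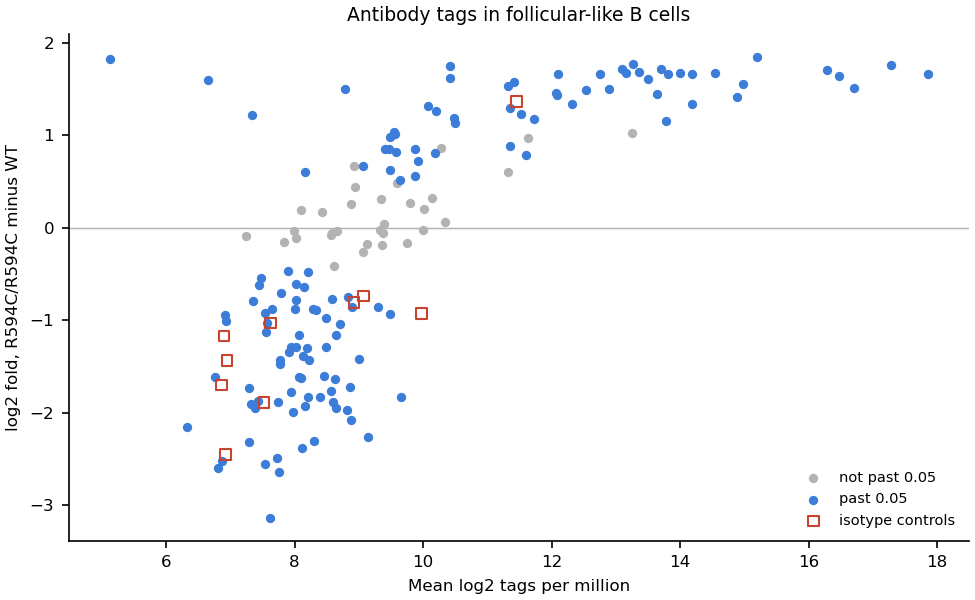
Antibody tags in follicular-like B cells: mean log2 CPM of the tags (x) against the log2 fold for R594C/R594C minus WT (y), 1 point per antibody, blue past 0.05 and red squares for the isotype controls. The 33 antibodies above the highest isotype control have a median of 1.61, and the other 137 a median of -0.78 with 29 called higher and 79 lower; 9 of the 10 isotype controls lie below 0 and 1 above.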

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

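The tests of antibody scaling, of myeloid RNA in B1-like cells, of free RNA within the 6 lymphoid classes and of the splits for CD8 T-like lists were chosen only after the results were seen, as were all tests in B1-like cells and the list tests in plasma cell-like and CD8 T-like cells.

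Some genes changed by a different amount in another class than in follicular-like B cells, by edgeR's interaction test (adjusted p from 0.00026 to 0.032; differences on the log2 scale). In marginal zone-like B cells Vim differed by -1.18 in R594C/R594C and -0.89 in R594C/+, Serpina3g differed by 0.80 in R594C/R594C, and Ighd and Ms4a4c by -0.35 and -0.63 in R594C/+. In B1-like cells of R594C/R594C the differences were -0.91 for Fcgr2b, -1.32 for Fcer1g, the shared signalling chain of Fc receptors, -0.71 for Rrbp1, -0.77 for Pycard, the inflammasome adaptor, -1.52 for Scimp, 1.44 for Hspb1, a small heat shock protein, 0.87 for Gm45153 and 0.69 for Retreg1. In plasma cell-like cells of R594C/R594C they were -1.19 for Isg20 and -1.48 for Cyp4f18, and in CD4 T-like cells of R594C/+ 0.46 for Ighm. Serpina3g, Ms4a4c, Fcer1g, Rrbp1, Hspb1, Pycard, Scimp and Retreg1 are named because of this test.

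Single replicates stood apart from the rest of their group by Dixon's test in 5 of the 158 groups of values tested, and chance gives about 5% of groups. Plasmacytoid dendritic-like cells made up 0.293% of cells in WT replicate 4 and 0.187% to 0.203% in the others. In marginal zone-like B cells of R594C/+ replicate 2, Rps29 was at 5397 CPM (5190 to 5224 in the others) and Vim at 16.2 CPM (24.7 to 26.1). In B1-like cells, Hbb-bs was at 9.52 CPM in WT replicate 3 (23.7 to 24.1) and App at 27.6 CPM in R594C/+ replicate 1 (23.8 to 24.4). Outside the comparisons, hashtags 3 and 4, which mark no replicate of R594C/R594C, had 405 and 369 UMIs in that capture, beside 1434937 and 1494962 for hashtags 1 and 2.

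Hemoglobin transcripts were higher in both mutant captures across B and T cell classes. Free RNA from 1 source keeps Hba-a1 and Hbb-bs in 1 ratio, and WT conventional dendritic-like cells held 0 Hba-a1 beside 20 Hbb-bs UMIs (smallest adjusted p of 21 Fisher's exact tests 0.0398), which argues against 1 source for all 7 classes. Among the 6 lymphoid classes the ratio varied by 1.66-fold at most within a capture (WT; 1.20 in R594C/+ and 1.63 in R594C/R594C), so free RNA in the droplets may account for the hemoglobin signal there. Doublets with erythroid cells would put many UMIs in few cells, but cells with 5 or more held 1.90% of the lymphoid Hbb-bs UMIs pooled over classes and captures, which argues against them as the main source, though in B1-like cells of R594C/R594C cells with 1 to 4 held only 82.5% of Hbb-bs and 84.4% of Hbb-bt UMIs, so a part from doublets stays open there. What made the captures differ stays open, since genotype, capture and, in part, sex cannot be told apart, and the ratios say nothing of the neutrophil transcripts. Hbb-bs in follicular-like B cells argues against sex. Female WT 2 had 140 UMIs in 1181 cells, and the WT males 100 to 140 in 944 to 1213. Male R594C/R594C 1 had 1062 in 3130, and female R594C/R594C 2 had 881 in 2623.

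Antibody tags changed in large numbers between R594C/R594C and WT in the 3 tested classes. At least 8 of the 10 isotype controls changed in each class, as a different staining background of the capture would give, so that background is a candidate explanation. The choice between TMM and RLE scaling over antibodies is argued against as the whole cause, because at least 80.7% of the calls remained with RLE. The tags that set the scale still matter, because with only the tags above the isotype controls 4, 0 and 0 passed by edgeR in follicular-like B, marginal zone-like B and CD4 T-like cells (5, 7 and 5 at an unadjusted p under 0.05; DESeq2 was not run). A difference in surface protein between genotypes was not told apart from the staining tube.

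In B1-like cells 23 genes were lower in R594C/R594C than in WT, several of them genes that myeloid cells also express. For RNA of monocyte-, macrophage-, neutrophil- or basophil-like or of conventional, activated or plasmacytoid dendritic-like cells to account for this, the leading marker would have to be at least 23.9 times its mean level over the WT replicates (Ly6c2 465.7 CPM needed, 19.5 measured and 48.0 in the highest, replicate 1; basophil-like Gata2 was at 0), which argues against these. For cluster 17, led by Il1b and Ptgs2, Ms4a6c would need 1.87 times (214.7 CPM against 114.8, and 127.7 in the highest replicate), under the bound of 2, so its RNA stays open, although it would have to make up 43.1% of the RNA and the myeloid genes Lyz2, Ctsb, Apoe and Fcer1g had a median change of -0.25 against -0.68 for the 23. Another mix of 3 sub-clusters is argued against, since within them the median log2 change of the 23 genes was -0.67, with all 23 below 0 in each. The 23 were picked as lower in these same samples, so their direction is no separate support. The sub-clusters were made without these genes and the age-associated B list, so a mix of cells that differ in those genes stays open. The total of 40 changed genes moved with single replicates left out, as given above, and genotype and capture stay open too.

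For R594C/+ minus WT, the 8 replicates can be split into groups of 4 in 35 ways. A share of 1 of 35 is the smallest these splits can give, and it was not adjusted over the counts tried. Every other split also mixes the WT and R594C/+ captures. Chance is therefore argued against, but not excluded, where no other split reached the real count. This held for genes in follicular-like B (37, highest other 3), marginal zone-like B (39, 2), plasma cell-like (8, 4), CD4 T-like (16, 2) and CD8 T-like cells (15, 9), for tags in follicular-like B (117, 9), marginal zone-like B (71, 0) and CD4 T-like cells (69, 4), and for lists in marginal zone-like B cells (9, 8). Those 9 lists stand close to 8, so chance stays open there. So it does for genes in B1-like cells, where another split reached the count (10, 14, in 2 of 35 splits). In conventional dendritic-like cells every split reaches the real count of 0 (35 of 35; highest other 9), so the splits say nothing there. For lists chance stays open in follicular-like B (12, 13, in 3 splits), CD4 T-like (8, 9, in 3) and conventional dendritic-like cells (7, 9, in 6). It also does in CD8 T-like (7, 11, in 6), B1-like (5, 10, in 9) and plasma cell-like cells (5, 9, in 11). Excluding chance leaves capture, which follows the same split, and sex, which nearly does (WT 2 is female by expressed sex). With expressed sex in the fit 68, 16 and 17 genes passed in follicular-like B, CD4 T-like and CD8 T-like cells. This argues against sex as the whole cause there, but marginal zone-like B and plasma cell-like cells had 23 and 2.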

How the results depend on the processing

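The choices made after the data were seen are named above. RLE scaling and stricter cell filters left each total of changed genes and tags they were run on within 1.5 times its value (RLE moved the split of tags into higher and lower, as given above), and no class share passed under any setting. Of 238 named genes and antibodies, counted by comparison, 2069 of 2379 values with a replicate left out kept their direction and side of the threshold, 295 lost the call and 15 turned; under the other settings 1849, 215 and 15 of 2079 did. A fit with R594C/R594C at 1 replicate assumes that it varies like the other groups. Simulated recovery was also 76% and 97% for R594C/+ in plasma cell-like cells (changes of 1 and 2 on the log2 scale). Except where the setting's own construction shows it (more genes tested with no filter, fewer tags or replicates), the cause was not tested.

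With a replicate left out, changed genes numbered 12 to 21 and 26 to 46 in follicular-like B cells for R594C/R594C and R594C/+ (reported 20 and 37), 16 to 79 between the mutant genotypes (62), 9 to 19 and 20 to 44 in marginal zone-like B cells (19 and 39), 4 to 80 and 8 to 11 in B1-like cells (40 and 10), 1 to 27 and 3 to 11 in plasma cell-like cells (9 and 8), 6 to 16 and 10 to 18 in CD4 T-like cells (9 and 16), 6 to 21 and 11 to 22 in CD8 T-like cells (10 and 15), and 0 to 8 in both comparisons of conventional dendritic-like cells (0 by edgeR and by DESeq2, 218 and 255 at an unadjusted p under 0.05). Tags numbered 131 to 139 and 102 to 135 in follicular-like B, 92 to 109 and 55 to 92 in marginal zone-like B, and 111 to 131 and 43 to 72 in CD4 T-like cells. The replicates behind each larger move of a gene or tag count are named above beside that count.

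Lists numbered 7 to 16, 10 to 14 and, between the mutant genotypes, 10 to 16 in follicular-like B cells with a replicate left out, 4 to 9 and 8 to 11 in marginal zone-like B, 11 to 15 and 4 to 6 in B1-like, 7 to 11 and 2 to 8 in plasma cell-like, 4 to 14 and 6 to 9 in CD4 T-like, 7 to 10 and 7 to 9 in CD8 T-like, and 3 to 8 and 5 to 9 in conventional dendritic-like cells. The larger moves were 7 and 10 without R594C/R594C replicate 2 in follicular-like B cells, against WT and R594C/+, and 4 and 5 without R594C/R594C replicates 1 and 2 in marginal zone-like B cells. For R594C/R594C they were 4 without replicate 2 in CD4 T-like cells and 3 without replicate 1 in conventional dendritic-like cells. For R594C/+ in plasma cell-like cells they were 3 and 8 without WT replicates 1 and 2, 3 and 2 without R594C/+ replicates 2 and 4, and 8 without R594C/R594C replicate 2.

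With no filter on low counts 32, 61 and 105 genes passed in follicular-like B cells (R594C/R594C, R594C/+, and between them), 118 and 21 in B1-like, 53 and 38 in plasma cell-like, and 45 and 39 in conventional dendritic-like cells. With expressed sex in the fit 68 passed for R594C/+ in follicular-like B cells, 137 between the mutant genotypes, 23 for R594C/+ in marginal zone-like B cells, 5 and 2 in plasma cell-like and 1 and 6 in conventional dendritic-like cells; tags were 14 and 41 for R594C/+ in marginal zone-like B and CD4 T-like cells, and lists 8 and 12 for R594C/R594C in follicular-like B and conventional dendritic-like cells. With doublets kept, 12, 20 and 19 genes passed for R594C/R594C in marginal zone-like B, plasma cell-like and CD4 T-like cells, and 6 for R594C/+ in B1-like cells. DESeq2 gave 9 and 13 in marginal zone-like B cells and, for R594C/R594C, 19, 4 and 6 in plasma cell-like, CD4 T-like and CD8 T-like cells. Classes from WT cells gave 5 for R594C/+ in plasma cell-like cells, and the margin rule and thinned counts gave 2 and 1 for R594C/R594C in conventional dendritic-like cells. Tags above the isotype controls are given above (6 for R594C/+ in follicular-like B cells at an unadjusted p under 0.05).

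With an estimated correlation in camera, lists passing were 3, 3 and 2 in follicular-like B cells, 2 and 2 in marginal zone-like B, 3 and 2 in B1-like, 0 and 2 in plasma cell-like, 2 and 2 in CD4 T-like, 3 and 3 in CD8 T-like, and 1 and 0 in conventional dendritic-like cells. Under fry they were 4 for R594C/R594C and 9 between the mutant genotypes in follicular-like B cells, 1 and 2 in marginal zone-like B, 4 and 2 in B1-like, 2 for R594C/R594C in plasma cell-like, 2 and 2 in CD4 T-like, 3 and 4 in CD8 T-like, and 1 and 0 in conventional dendritic-like cells.

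Same-numbered WT and R594C/+ replicates had correlations of deviations of 0.17, -0.10, -0.058 and 0.045, and of the WT replicates, number 1 alone correlated best with its own number. Against R594C/R594C they were 0.21 and 0.60, where 2 replicates mirror each other (-0.21 and -0.60 crossed), and WT 2 and R594C/R594C 2 are both female by expressed sex. Not every pair passed 0.1, so the numbers were not taken to pair the samples. With the replicate number as a block, 16 genes passed for R594C/+ in B1-like cells, 14 and 22 in plasma cell-like, 23 for R594C/+ in CD8 T-like, and 4 and 9 in conventional dendritic-like cells; the other counts stayed within 1.5 times. The values that turned under the block were the correlation of the CD4 T-like share of cells with alleles (0.0988), Ern1 between the mutant genotypes in follicular-like B cells (-0.22), Xbp1 in B1-like cells for R594C/+ (0.022) and Xbp1 in CD8 T-like cells for R594C/R594C (-0.0049).

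Other values that turned were, apart from S100a9, Jchain, Ccl5 and Cd74, values that had not passed a test. The correlation with alleles of the share of cells, CD4 T-like, was 0.0263 under the margin rule and 0.0389 with classes from WT cells. With a replicate left out, correlations of shares that turned were 0.0029 to 0.0408 for B1-like, 0.00476 to 0.0868 for CD4 T-like, -0.138 for CD8 T-like, -0.289 for follicular-like B and 0.0113 to 0.051 for plasma cell-like cells. Over all replicates left out, these correlations ran from -0.417 to 0.0408, -0.421 to 0.0868, -0.138 to 0.26, -0.289 to 0.401 and -0.374 to 0.051. Ern1 in follicular-like B cells for R594C/R594C was 0.22 with classes from WT cells and 0.057 to 0.20 where a left-out replicate turned it (-0.38 to 0.20 over all), and -0.045 to -0.030 between the mutant genotypes (-0.045 to 0.54). Ern1 in plasma cell-like cells for R594C/+ was -0.088 to -0.021 (-0.088 to 0.36). Xbp1 with a replicate left out was 0.064 in follicular-like B cells for R594C/R594C (-0.17 to 0.064), 0.053 to 0.073 in B1-like cells for R594C/+ (-0.10 to 0.073) and 0.041 to 0.047 in CD4 T-like cells for R594C/R594C (-0.091 to 0.047). Xbp1 was also 0.045 with classes from WT cells and 0.032 with thinned counts in B1-like cells for R594C/+, and 0.0031 with no filter in CD4 T-like cells for R594C/R594C. With expressed sex in the fit Xbp1 for R594C/+ was -0.0038, -0.061 and -0.054 in follicular-like B, plasma cell-like and conventional dendritic-like cells. With doublets kept, S100a9 and Jchain in B1-like cells were -0.79 (R594C/R594C) and -0.99 (R594C/+), and in CD8 T-like cells Ccl5 was 0.11 and Cd74 0.015 for R594C/R594C and Cd74 0.029 for R594C/+.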

Other observations

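The counts of changed genes in classes outside the planned ones, and the plasma cell isotypes, were chosen only after the data were seen, and replicates were not left out in turn for them. Among 25 classes tested with edgeR, neutrophil-like cells, short-lived phagocytes, had the most changed genes between R594C/+ and WT. There 84 genes rose and 57 fell of 2119 (719 at an unadjusted p under 0.05; 262 changed by DESeq2), but 0 passed by edgeR with expressed sex in the fit. The class joins cluster 24, at 0.718%, 0.579% and 0.898% of cells in WT, R594C/+ and R594C/R594C, and cluster 33, led by the granule genes Camp, Ngp and Ltf, at 0.0484%, 0.633% and 0.216%, so these counts do not separate a change within cells from the mix of the 2 clusters. Between R594C/R594C and WT 0 passed (77 at an unadjusted p under 0.05; 0 by DESeq2), and the difference between the comparisons was not tested. In regulatory T-like cells, which restrain other T cells, 13 rose and 2 fell of 5861 in R594C/+ (395 at an unadjusted p under 0.05; 4 by DESeq2; 0 by edgeR with expressed sex), and 1 rose in R594C/R594C (0 by DESeq2). Cluster 7 holds T cells with 7 of 8 CD8 T markers, led by the effector genes Ccl5, Nkg7 and Klrk1. It had 13 higher and 9 lower of 8122 in R594C/+ (15 by DESeq2, 10 with expressed sex). In R594C/R594C it had 2 and 3 (9 in all with expressed sex). NK-like cells had 8 higher and 4 lower in R594C/+ (10 by DESeq2, 4 with expressed sex). Cluster 10, led by the growth genes Ncl, Mif and Nme1, had 13 and 2 in R594C/+ (7 in all with expressed sex) and 8 and 2 in R594C/R594C (5 in all by DESeq2). In germinal centre-like B cells, which arise during antibody responses, 1 gene rose in R594C/+ (2 by DESeq2; 1 higher and 11 lower with expressed sex) and 0 changed in R594C/R594C by edgeR (327 at an unadjusted p under 0.05; 0 by DESeq2; 1 lower with expressed sex).

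Plasma cell-like cells were also grouped by the heavy chain constant gene with the most UMIs. Of 238 cells in WT, 407 in R594C/+ and 164 in R594C/R594C, pooled over replicates, Ighm led in 65.1%, 64.4% and 61.6%. Ighg3, the IgG3 constant gene, led in 12, 32 and 37 cells (5.04%, 7.86% and 22.6%) and Ighg2c in 24, 39 and 3 (10.1%, 9.58% and 1.83%). Ighg2b led in 24, 45 and 7 cells, Igha in 18, 20 and 14, and Ighg1 in 5, 9 and 2. These numbers were not tested across replicates. Cluster 7 made up 6.12% of cells in WT, 4.07% in R594C/+ and 3.2% in R594C/R594C (exact permutation p of the trend 0.0356 before and 0.886 after adjustment over 31 classes). Erythroid-like cells made up 0.274%, 0.869% and 0.599%, and cluster 9, T cells led by Tnfsf8, Spry1 and Maf with 5 of 7 regulatory T markers beside 7 of 8 CD4 T markers (Izumo1r, Tnfrsf4 and Ctla4 among its top 10 genes), 4.41%, 5.94% and 2.77% (exact permutation p of the F statistic 0.0203 for each, 0.307 after adjustment).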
